A study of Mus musculus with 8 samples.

How the data were processed

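Chromatin accessibility was measured by ATAC-seq, in which a transposase cuts open DNA and leaves sequencing adapters there. The cells were flow-sorted from C57BL/6 mice whose Foxp3 gene carries a red fluorescent protein (RFP) reporter, so that RFP marks regulatory T cells (Tregs). The 8 libraries fall into 4 groups of 2: RFP-positive Tregs of male spleen, of male visceral adipose tissue (VAT) and of female VAT, and RFP-negative CD4 T cells of male VAT. Per the labels, each library came from cells pooled from 3 mice. The design text also speaks of female spleen, but the labels give both spleen libraries as male, and the Y-linked counts given with the results were used to check this.

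The authors deposited 1 table of raw counts per region for all libraries, with no normalisation. Per the labels the build is mm10 (GRCm38). The submitters' processing notes name Subread 1.6.2, HOMER 4.9, featureCounts and limma without saying what each was used for, and how the regions were called is not stated. The authors also deposited 1 file per library of log2 CPM, where CPM is the count of a region scaled to the library total. Tested on the files, each of those values equals log2 CPM with 0.5 added to the count and 1 to the library total, shifted by 1 constant per library, and 3511 entries of the count table are left out of them. The deposited log2 values were used for 1 alternative, and the raw counts for everything else.

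The count table has 62205 entries for 46624 distinct regions, because 10063 regions are listed once for each of several genes, and these were reduced to 1 entry per region. Regions kept the genes that the table assigns to them, so a region said to be at a gene can lie far from it. No 50 kb limit to a transcription start could be set, since the gene table at hand gives gene bodies without strand; of 19714 gene identifiers in the count table, 18560 were found in it, and 61.4% of the regions kept lay inside a gene they were assigned to. Coordinates are printed as the table gives them, and whether starts count from 0 or from 1 is not stated. Left out were the mitochondrial region, unplaced sequence, and 111 regions without a gene. Of 46512 regions on chromosomes 1 to 19, X and Y, edgeR's filterByExpr kept 45709: 44691 autosomal, 991 on X and 27 on Y. Widths fall into 2 classes, 16363 regions under 1000 bp (median 121 bp) and 29346 of 1000 bp or more (median 3693 bp).

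Counts used ranged from 5724685 to 15805270 per library. CPM were scaled with trimmed-mean-of-M (TMM) factors, which ran from 0.907 to 1.06. All 8 libraries entered 1 edgeR 4.0.16 quasi-likelihood fit (R 4.3.3) with a coefficient per group and 4 residual degrees of freedom, and each comparison was a quasi-likelihood F test with Benjamini-Hochberg adjustment over all regions kept. A region was called at an adjusted p under 0.05. The ± after a log2 fold change is an approximate standard error, the log2 fold change divided by the square root of its F statistic. The ± after a CPM value is the SD of 2 libraries, and n is 2 in each group throughout. Where a group had 0 counts at a region, the fold is a lower bound against a floor of 3 counts over that group; where it had 1 to 3, the ratio of summed counts is given with an exact 95% interval. Floors and intervals cover counting error only, since reads carry no molecular identifiers. No batch labels are given. Replicate numbers were not taken to pair libraries across groups.

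In all, 22 gene lists with 406 genes were tested with camera (limma 3.58.1) on the regions of each list at a preset correlation of 0.01, adjusted by Benjamini-Hochberg over the lists, and again with an estimated correlation. The lists were VAT Treg genes, Treg core genes, naive and lymphoid homing genes, Th1, Th2 and Th17 genes, chemokine receptors, cytokine receptors, TNF receptors and costimulation, AP-1 and IRF factors, NF-kB factors, activation and exhaustion factors, lipid metabolism genes, steroid hormone genes, tissue repair and suppressive effectors, X-linked escape genes, Y-linked genes, and markers of B cells, of myeloid cells, of CD8 and NK cells, of adipocytes and of stromal and endothelial cells. Of the 64 genes on the last 5 lists, 3 stand on another list too. Regions are not independent replicates.

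Genes were named by a rule: per comparison the 10 genes with the largest log2 fold change in each direction among called autosomal regions in which both libraries of a group lie above both of the other (predicted genes left out), up to 4 called genes per list, the genes Foxp3, Il1rl1, Pparg, Klrg1, Ccr2, Il10, Gata3, Prdm1 and Tcf7 in each comparison, and 8 sex-linked genes. The comparisons, tests, lists, this rule and most alternatives were chosen before the data were examined. The T cell receptor alpha locus and a set of regions read in every male library were singled out after their values were seen.

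The alternatives were DESeq2 size factors, library size alone, TMM on autosomal regions, loess offsets, no low-count filter, a filter at 2 CPM, the DESeq2 1.42.0 Wald test, limma-voom, a fit of the compared groups alone, the replicate number as a block, an adjusted p under 0.01, a 2-fold minimum, genes within 20 kb for the lists, and each of the 8 libraries left out in turn. Where that left a group with 1 library, the lone library was taken to vary like the other groups. TMM on regions under 1000 bp and limma on the deposited log2 values were added after the data were seen. A correction for GC content and a search for sequence motifs were not run, since they need a genome sequence, and promoter-only lists were not run, since they need transcription starts.

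The pipeline was tested on simulated data: counts were drawn from each region's mean over the 8 libraries and its fitted dispersion, with 100 regions changed 2-fold and 100 changed 4-fold in each comparison. At 2-fold 50 to 60 were found, at 4-fold 84 to 91, with 0 wrong directions and 2.16 to 6.96% of calls false. The draw held no differences in quality between libraries, so these rates describe the simulated data alone. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.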

Results

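The series asks how open chromatin of regulatory T cells (Tregs) differs between male and female visceral adipose tissue (VAT). ATAC-seq counts over 45709 regions were compared in 8 libraries, 2 of each group. The groups were male spleen Tregs, male VAT Tregs, female VAT Tregs and male VAT CD4 T cells negative for the Foxp3 reporter. Counts used were 8206795 and 15805270 in spleen Tregs, 15201918 and 9308538 in male VAT Tregs, 9955944 and 8354378 in female VAT Tregs, and 5724685 and 7231281 in VAT CD4 cells. Over regions under 1000 bp, Pearson's r across regions of log2 CPM was 0.706 to 0.791 within groups and 0.380 to 0.696 between groups. Regions are not independent replicates. Male VAT Treg replicate 1 had 5.63% of its counts in regions under 1000 bp, against 4.27% in replicate 2 and 3.64 to 4.42% in the libraries of the other groups.

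**Figure D1:**
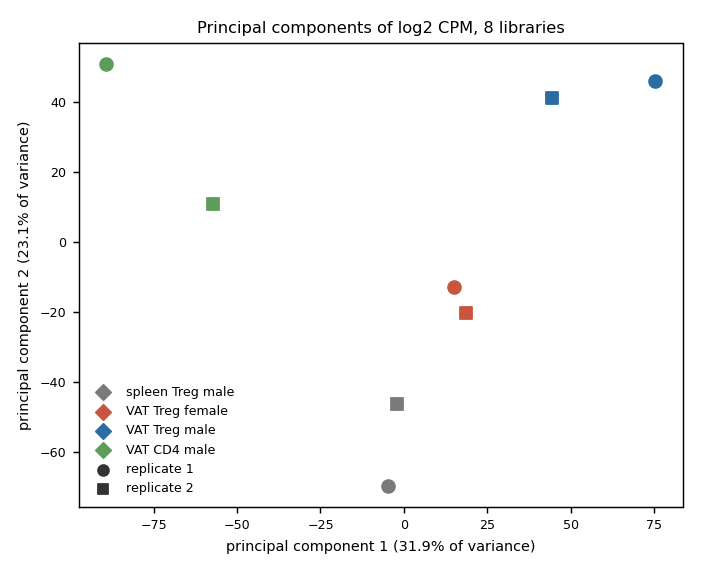
First and second principal components of log2 CPM over the autosomal regions, in the units of the scores. Each point is a library, coloured by group and shaped by replicate. The first component held 31.9% of the variance, with VAT CD4 cells at the left and male VAT Tregs at the right, and the second held 23.1%, with female VAT Tregs between spleen and male VAT Tregs on it.

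Sex-linked genes matched the sex on the labels in all 8 libraries. Uty, a Y-linked histone demethylase gene, had 11.14 to 19.03 CPM in the male libraries and 0 counts in the female libraries, at least 92.2-fold higher in males against a floor of 3 counts over the female group. Ddx3y and Eif2s3y, both Y-linked, had 3 and 5 counts in females against male means of 15.9 and 13.2 CPM. The region of Xist, the RNA that silences an X chromosome, on chromosome X from 103481725 to 103481960 held 4.49 and 7.04 CPM in the female libraries and at most 0.963 CPM in a male library. Kdm5c and Kdm6a, genes known to escape X inactivation, held 54.2 and 65.7 CPM in females and 23.9 and 39.7 CPM in males. Kdm5d had no region in the table.

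Male VAT Tregs were compared with female VAT Tregs for the sex difference that the series title names. Regions at Klrg1, Ctsh and Plin2 were higher in males. At Klrg1, an inhibitory receptor of differentiated T cells, the region on chromosome 6 from 122283454 to 122283971 held 11.7 ± 6.25 CPM in males and 1.55 ± 0.788 CPM in females (log2 fold change 2.95 ± 0.37, n = 2 per group, edgeR quasi-likelihood test with Benjamini-Hochberg adjusted p = 1.53e-11). At Ctsh, which encodes the lysosomal protease cathepsin H, chromosome 9 from 90070916 to 90071323 held 9.28 ± 4.53 against 0.851 ± 0.207 CPM (3.44 ± 0.44). At Plin2, whose product coats lipid droplets, chromosome 4 from 86690207 to 86690556 held 10.001 ± 4.49 against 1.33 ± 0.382 CPM (2.91 ± 0.40). Lower in males was a region of the T cell receptor alpha segment Trav17, at 0.382 ± 0.0874 against 2.57 ± 0.315 CPM (-2.67 ± 0.57). These 4 regions kept their calls in each fit that left out a library.

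The list of VAT Treg genes had 21 of 148 regions higher and 0 lower in males, at 9 of its 24 genes. Adjusted over the list alone, 41 were higher and 3 lower (camera adjusted p = 3.37e-13, and adjusted p = 0.711 with an estimated correlation). Without male replicate 1 the list's test still passed at an adjusted p of 0.0367, with 5 regions higher and 1 lower. Klrg1 had 4 of 9 regions higher. Il1rl1, the IL-33 receptor, had 3 of 9 higher, with 7.50 ± 7.14 against 2.18 ± 0.589 CPM at the leading region (1.82 ± 0.39). Pparg, a nuclear receptor of fat cells and fat Tregs, had 1 of 4 (5.31 ± 2.98 against 1.12 ± 0.253 CPM, 2.25 ± 0.49). Il10, an anti-inflammatory cytokine, had 2 of 12 (6.84 ± 4.84 against 1.70 ± 0.415 CPM, 2.03 ± 0.41). Prdm1, which encodes the effector factor Blimp-1, had 2 of 16 higher, led 148 kb from the gene (8.80 ± 2.79 against 2.87 ± 1.09 CPM, 1.65 ± 0.34). These 4 calls were lost without male replicate 1. Without it the log2 fold changes were 0.16, 1.50, 0.99 and 1.27, with adjusted p of 0.949, 0.360, 0.466 and 0.0792 in edgeR. Without female replicate 2 the calls of Il1rl1, Pparg and Il10 were lost at adjusted p of 0.108, 0.0846 and 0.0562, and without female replicate 1 that of Prdm1 at 0.162. At Il1rl1 the DESeq2 Wald test gave an adjusted p of 0.146, and edgeR scaled on regions under 1000 bp gave 0.0537. Ccr2 is a chemokine receptor, Gata3 a Th2 factor that VAT Tregs also use, and Tcf7 encodes the naive cell factor TCF-1. These genes had 0 called regions by edgeR, DESeq2 and limma-voom. In edgeR 0, 0 and 2 of their regions were lower at an unadjusted p under 0.05. The 2 regions assigned to Ccr2 lay 21.9 and 33.2 kb from the gene, so Ccr2 itself was not measured in any comparison.

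**Figure D2:**
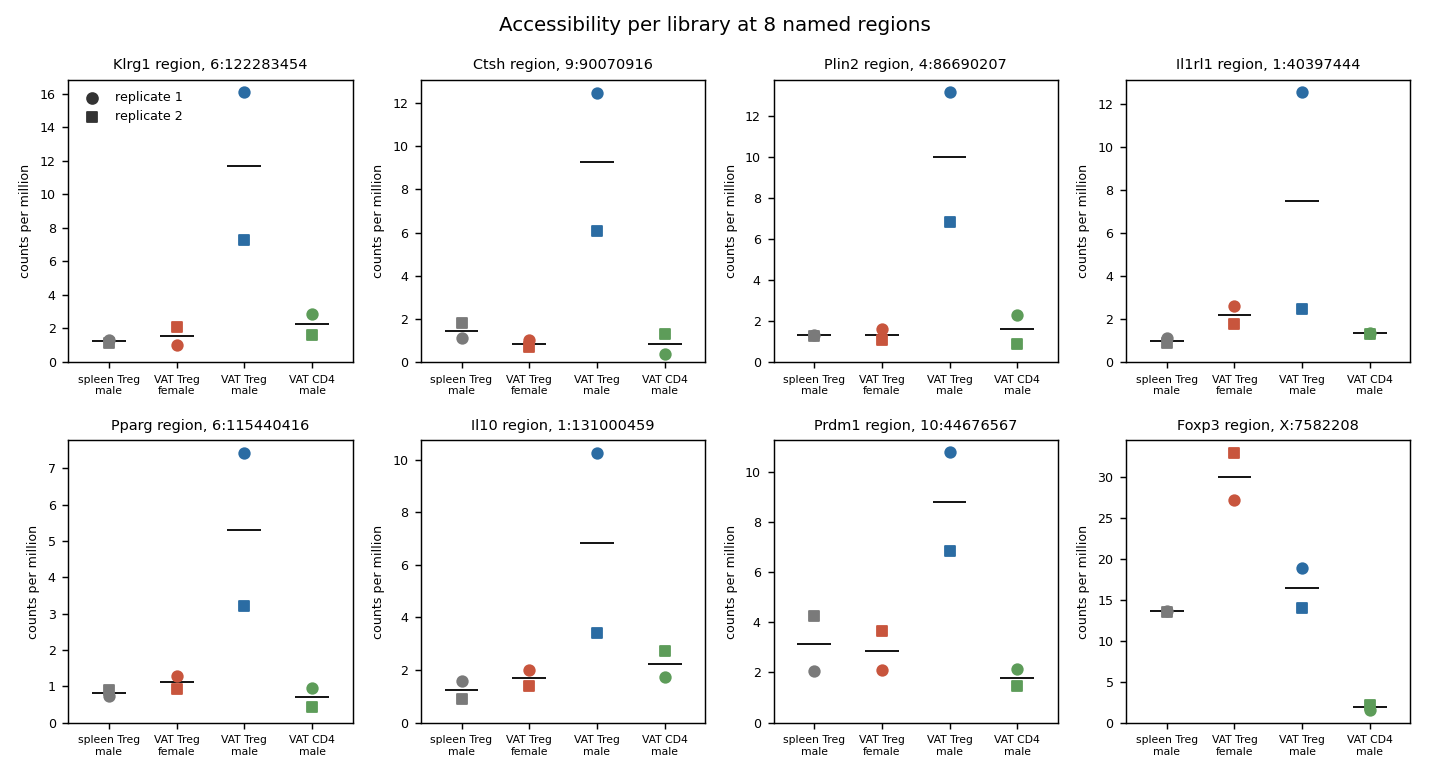
CPM at 8 named regions, titled by gene, chromosome and start; points are libraries (circle replicate 1, square replicate 2) and black lines the mean of 2. At Klrg1, Ctsh and Plin2 both male VAT Treg libraries lie above all others, and at Il1rl1 male VAT Treg replicate 1 lies far above replicate 2.

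Foxp3, the X-linked Treg factor, had 3 of 6 regions lower in males, with 16.4 ± 3.43 against 30.0 ± 4.05 CPM on chromosome X from 7582208 to 7585993 (-0.86 ± 0.20). Over all 991 X regions the median log2 fold change was -0.59, and 82.7% lay below 0, against 0.01 for autosomal regions. On X, 220 regions were lower and 1 higher in males. The Foxp3 call was lost without female replicate 2 (adjusted p = 0.227, edgeR) and without male replicate 2 (0.0727).

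Th17 genes had 5 of 41 regions higher and 0 lower (9 and 0 adjusted over the list alone, camera adjusted p = 0.00186, and adjusted p = 0.711 with an estimated correlation). They were led by Il17a, the gene of the cytokine IL-17A, at 13.5 ± 2.71 against 3.81 ± 0.402 CPM (1.83 ± 0.28). Cytokine receptors had 13 of 158 higher and 0 lower (17 and 2, 0.00294, and adjusted p = 0.806 with an estimated correlation). Among them was Il17ra, a chain of the IL-17 receptor, at 2.68 ± 0.37. Activation and exhaustion factors had 10 of 131 higher and 0 lower (12 and 0, 0.00789, and adjusted p = 0.806 with an estimated correlation). Zeb2, a repressor of effector cells, led them at 2.59 ± 0.37. NF-kB factors had 6 of 91 higher and 0 lower (11 and 1, 0.000347, and adjusted p = 0.806 with an estimated correlation). Th2 genes had 3 of 53 higher, all at Il1rl1, and 0 lower (6 and 2, 0.00235, and again adjusted p = 0.806 with an estimated correlation). Without male replicate 1 these 5 list tests gave adjusted p of 0.631, 0.952, 0.701, 0.701 with the NF-kB direction turned, and 0.952. The regions of Il17a, Il17ra and Zeb2 kept their calls without any 1 library, as did that of the interferon regulatory factor Irf8 at 1.37 ± 0.24.

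Chemokine receptors had 0 of 77 regions higher and 3 lower in males (0 and 5 adjusted over the list alone, camera adjusted p = 0.0133, and adjusted p = 0.806 with an estimated correlation). Naive and lymphoid homing genes had 3 higher and 3 lower of 128 (5 and 5, 0.0399, direction down, and adjusted p = 0.806 with an estimated correlation). Cxcr5, a homing receptor for B cell follicles, held 8.32 ± 1.05 against 15.9 ± 0.0117 CPM (-0.92 ± 0.23), a call lost without female replicate 1 or 2 (adjusted p of 0.127 and 0.102, edgeR), without male replicate 2 (0.0580) and in the DESeq2 Wald test (0.0737). The chemokine list test was lost without male replicate 2 (0.408), and the naive list test without female replicate 2 (0.111) or male replicate 2 (0.447). B cell markers had 0 called regions of 24 by edgeR, DESeq2 and limma-voom, 0 higher and 4 lower at an unadjusted p under 0.05 in edgeR, and a camera adjusted p of 0.00235 downwards (adjusted p = 0.473 with an estimated correlation). Over the 115 regions of the 5 lists of other cell types edgeR called 0 higher and 1 lower, at Cd68, a call lost without female replicate 1 or 2 (0.130 and 0.0646) or male replicate 2 (0.0524). There 5 higher and 9 lower had an unadjusted p under 0.05, DESeq2 called 0 and 1, and limma-voom 0 and 1. X-linked escape genes had 30 of 42 regions lower and Y-linked genes 3 of 4 higher in males, each with an adjusted p of 0.00306 with an estimated correlation. The other lists did not pass: Treg core genes (camera adjusted p = 0.778), Th1 genes (0.242), TNF receptors and costimulation (0.276), AP-1 and IRF factors (0.621), lipid metabolism genes (0.793), steroid hormone genes (0.841), tissue repair and suppressive effectors (0.141), and markers of myeloid cells (0.168), CD8 and NK cells (0.671), adipocytes (0.0615) and stromal and endothelial cells (0.887). Lipid metabolism genes had a median of -0.04 and a mean of 0.12 with the test downwards, and stromal markers -0.01 and 0.06 with the test downwards.

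The largest male-higher fold changes were at short regions with few female counts. Jdp2, a repressor of the AP-1 family, was at least 16.2-fold higher in males (66 counts against 0). Rad51b, a recombination gene, had 178 counts against 4, a ratio of 32.8 with a 95% interval of 12.6 to 122. Prkag2, a subunit of the energy sensor AMPK, had 80 against 2, a ratio of 29.5 (7.90 to 248). Hhex, a homeobox repressor, held 4.20 ± 0.389 against 0.267 ± 0.0456 CPM. The calls of the other 6, at Htr6 and Tmco4, Bbs9, Bbs10, Zhx1, Slc25a1 and Tfpi, were lost without at least 1 library. The regions of Bbs10, Slc25a1 and Tfpi lay 59.5, 21.3 and 17.1 kb from these genes. Jdp2, Prkag2, Bbs10 and Htr6 belong to 12 short autosomal regions, chosen after their values were seen, that had at least 0.5 CPM in each of the 6 male libraries, VAT or spleen, Treg or not, and a mean of the 2 female libraries under 25% of the lowest male value. Of the 10 largest lower in males, 8 lay in the T cell receptor alpha locus. The call of Trav17 held, and those of the other 7, at Trav8-2, Trav6-7-dv9, Trdc with Traj segments, Trav21, Trav14-3, Trav13-2 and Trav14-1, were each lost without at least 1 library, at adjusted p of up to 0.823 (Trdc, edgeR). Outside the locus were Skap1, an adaptor of T cell receptor signalling (-2.26 ± 0.54, lost without female replicate 2 at an adjusted p of 0.428), and Pde2a, a cyclic nucleotide phosphodiesterase, lost without female replicate 1 or 2 (0.365 and 0.325) or male replicate 1 or 2 (0.149 and 0.173).

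Of autosomal regions under 1000 bp, edgeR called 762 higher and 32 lower in male than in female VAT Tregs. Of those of 1000 bp or more it called 162 higher and 303 lower. An unadjusted p under 0.05 was found at 5629 autosomal regions. In all, edgeR called 924 autosomal regions higher and 335 lower in male than in female VAT Tregs, 73.4% of them higher. The split turned over without male VAT Treg replicate 1, with 224 higher and 941 lower. The counts were 1245 and 164 without male replicate 2, 263 and 62 without female replicate 1, and 304 and 16 without female replicate 2. Of the 924 higher regions, 922 could be tested without male replicate 1, all 922 still with a fold change above 0 and 206 still called. Both male libraries took part in choosing them. The DESeq2 Wald test called 346 higher and 47 lower.

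**Figure D3:**
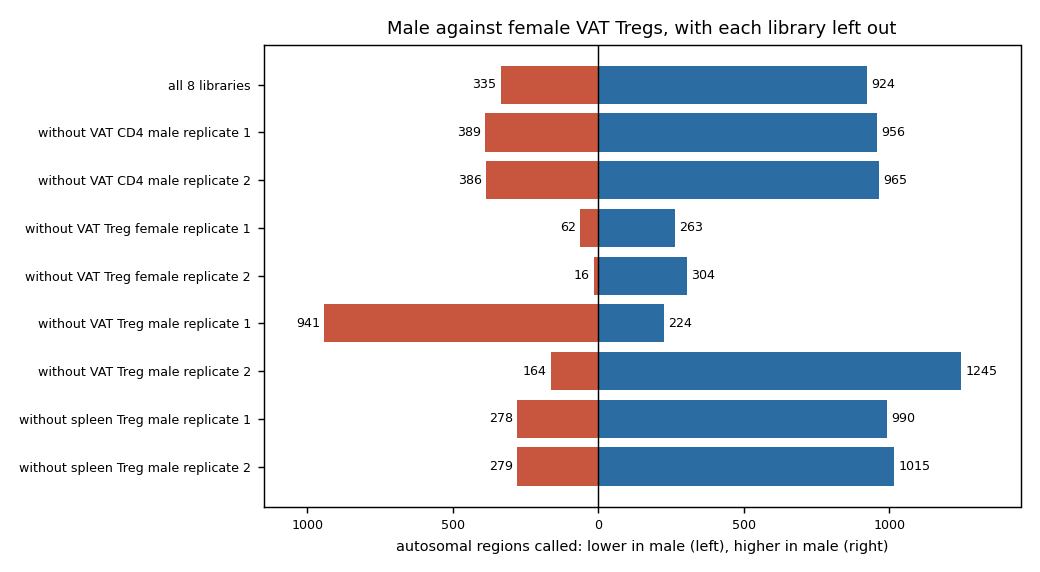
Autosomal regions called by edgeR in male against female VAT Tregs, with all 8 libraries and with each left out; bars to the right count regions higher in males and bars to the left regions lower in males. Without male VAT Treg replicate 1 the counts are 224 and 941, against 924 and 335 with all libraries.

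Male VAT Tregs were compared with male spleen Tregs for the difference between tissues within a sex. Regions at Il4ra, Tnfaip3 and Pdcd1 were higher in fat. Il4ra, the shared chain of the IL-4 and IL-13 receptors, held 42.7 ± 15.1 CPM in VAT and 12.1 ± 0.555 CPM in spleen on chromosome 7 from 125579795 to 125582888 (log2 fold change 1.84 ± 0.20, n = 2 per group, edgeR quasi-likelihood test with Benjamini-Hochberg adjusted p = 1.78e-15). Tnfaip3, which encodes the NF-kB inhibitor A20, held 11.7 ± 5.23 against 1.44 ± 0.665 CPM on chromosome 10 from 19001610 to 19002603 (2.93 ± 0.32), and Pdcd1, which encodes PD-1, 22.9 ± 7.21 against 5.96 ± 0.0214 CPM (1.95 ± 0.23). Lower in fat were Ccr7, the lymph node homing receptor, at 4.55 ± 1.00 against 10.2 ± 0.662 CPM (-1.13 ± 0.26), and Lif, an IL-6 family cytokine, at 2.80 ± 0.341 against 9.14 ± 0.243 CPM (-1.69 ± 0.30).

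VAT Treg genes had 53 of 148 regions higher and 2 lower in fat (68 and 7 adjusted over the list alone, camera adjusted p = 2.86e-17, and adjusted p = 0.817 with an estimated correlation), at 14 genes higher and 2 in both directions. Klrg1 had 6 of 9 regions higher, led by 11.7 ± 6.25 against 1.23 ± 0.141 CPM (3.28 ± 0.37). Also higher were Rora, a nuclear receptor of Th17 and tissue lymphocytes (2.29 ± 0.31), Nfil3, a basic leucine zipper factor (1.87 ± 0.26), and Plin2 (2.97 ± 0.39). Il1rl1 had 5 of 9 higher (2.98 ± 0.43), Pparg 1 of 4 (2.69 ± 0.49) and Il10 5 higher and 1 lower of 12 (2.58 ± 0.42). Gata3 had 2 higher and 1 lower of 13 (1.22 ± 0.31, 283 kb from the gene) and Prdm1 3 of 16 (1.42 ± 0.32, 148 kb from the gene). Without male VAT Treg replicate 1 these 5 regions gave adjusted p of 0.285, 0.140, 0.134, 0.143 and 0.128 in edgeR. Without spleen replicate 1 Gata3 gave 0.157 and Prdm1 0.103, and the DESeq2 Wald test gave 0.0947 for Gata3. Tcf7 had 2 of 9 lower, led 30.7 kb from the gene (-1.17 ± 0.33). That call was lost without male VAT Treg replicate 2 or spleen replicate 2 and in the DESeq2 Wald test (0.0933). Ccr2 had 0 of 2 called by edgeR, DESeq2 and limma-voom, and 1 higher at an unadjusted p under 0.05. Of 6 regions assigned to Foxp3, 1 was higher (49 counts against 2, ratio 24.3, interval 6.39 to 207). It lay inside the neighbouring gene Ppp1r3f, on chromosome X from 7565611 to 7565716, and its call was lost without male VAT Treg replicate 1. The region inside Foxp3 from 7582208 to 7585993 was not called, at 16.4 ± 3.43 CPM in VAT and 13.6 ± 0.0174 CPM in spleen.

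NF-kB factors had 28 of 91 regions higher and 0 lower (32 and 0 adjusted over the list alone, camera adjusted p = 2.47e-14, and adjusted p = 0.817 with an estimated correlation). Nfkb1, an NF-kB subunit gene, was at 3.16 ± 0.46, Birc3, an apoptosis inhibitor, at 1.11 ± 0.17 and Nfkbiz, a nuclear co-regulator, at 2.17 ± 0.36. Th17 genes had 14 higher and 1 lower of 41 (18 and 2, 7.38e-07, and adjusted p = 0.817 with an estimated correlation), with Il17a at 1.46 ± 0.26. Cytokine receptors had 24 higher and 3 lower (31 and 7, 0.00146, and adjusted p = 0.944 with an estimated correlation), with Il1rl2, the IL-36 receptor, at 3.32 ± 0.42 and Il17ra at 2.89 ± 0.36. Th2 genes had 10 and 1 (18 and 3, 0.00205, and adjusted p = 0.944 with an estimated correlation), led by Il4ra. Th1 genes had 17 and 1 of 76 (20 and 10, 0.00313, and adjusted p = 0.944 with an estimated correlation), with Hopx, a homeodomain protein of effector cells, at 108 counts against 3 (ratio 35.8, interval 11.9 to 176) and Il18rap, an IL-18 receptor chain, at 2.18 ± 0.37. For these 3 lists the fit without male VAT Treg replicate 1 gave adjusted p of 0.537, 0.588 and 0.537. Among lists that did not pass, AP-1 factors Fosl2 (1.31 ± 0.18) and Atf3 (1.29 ± 0.18), the co-stimulator Tnfrsf9, also named 4-1BB (1.28 ± 0.19), the exhaustion factor Tox (1.32 ± 0.20), the fatty acid elongase Elovl6 (2.35 ± 0.30) and the protease Furin (2.82 ± 0.31) were higher without any 1 library.

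Naive and lymphoid homing genes had 7 regions higher and 13 lower of 128 in fat (10 and 18 adjusted over the list alone, camera adjusted p = 0.0453, and adjusted p = 0.944 with an estimated correlation), with Il6ra, the IL-6 receptor, at -2.02 ± 0.48. That list test was lost without male VAT Treg replicate 2 (0.405) or spleen replicate 2 (0.187), and with scaling on regions under 1000 bp (0.0653). B cell markers had 0 higher and 2 lower of 24, at Pou2af1 and Cr2 (adjusted p = 0.00205, and adjusted p = 0.817 with an estimated correlation). The Pou2af1 call was lost without male VAT Treg replicate 1 (0.0610) or spleen replicate 1 (0.183), and that of Cr2 without female replicate 1 or 2 (0.0703 and 0.0643), male VAT Treg replicate 1 (0.286), spleen replicate 1 (0.0978) or spleen replicate 2 (0.277). Over the 5 lists of other cell types edgeR called 0 higher and 6 lower of 115 in fat, with 7 and 13 at an unadjusted p under 0.05, 0 and 1 by DESeq2 and 1 and 6 by limma-voom. The other 14 lists had camera adjusted p of 0.0640 to 0.997. Medians and means differed in sign for TNF receptors, activation factors and lipid genes, whose tests went up with medians of -0.03, -0.02 and -0.06, and the chemokine receptor test went down with a median of 0.01 and a mean of 0.03.

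Among the largest fold changes, the lipase gene Lipk held 18.8 ± 6.55 CPM in fat and 0.331 ± 0.0461 CPM in spleen (503 counts against 8, ratio 62.5). Mef2a, a MADS-box factor, and Zhx1 were at least 22.8-fold higher in fat, each against 0 spleen counts. Pisd (75 against 1 count, ratio 74.5, interval 13.0 to 2982), Tmem8b and Olfr70 (127 against 2, 63.1, 17.1 to 527), Slc36a2 and Slc36a3 (69 against 1, 68.5, 11.9 to 2746), Ghrh and Manbal (117 against 2, 58.1, 15.7 to 486) and Pcyt1a (128 against 3, 42.4, 14.2 to 208) followed. Lower in fat were Fam221a (-2.69 ± 0.55) and D16Ertd472e (-2.58 ± 0.47), whose calls held in each leave-one-out fit. The calls of Tnrc6a in fat and of Rasgrp1, Prl6a1, Cts6, Psmb10 with its neighbours, Lrp1b, Lrrc3b, Anxa8 and Tpst2 in spleen were each lost without at least 1 library. The regions of Lrp1b, Lrrc3b and Rasgrp1 lay 278, 142 and 60.7 kb from these genes.

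Of autosomal regions under 1000 bp, 1635 were higher and 173 lower in male VAT Tregs. Of those of 1000 bp or more, 450 were higher and 777 lower. In all, 2085 autosomal regions were higher and 950 lower, 68.7% of them higher, with 8386 at an unadjusted p under 0.05 in edgeR. Without male VAT Treg replicate 1 the counts were 704 and 988, or 41.6% higher, and scaling on regions under 1000 bp gave 1230 and 1288, or 48.8%. Without spleen replicate 1 they were 1378 and 310, and without spleen replicate 2 they were 1137 and 442. Without female replicate 1 and 2 the lower counts were 616 and 652. Of the 2085 higher regions, 2065 could be tested without male VAT Treg replicate 1, 2060 of them with a fold change above 0 and 638 still called.

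Female VAT Tregs were compared with male spleen Tregs, the one spleen group in the series, so that tissue and sex differ together. Regions at Tnfaip3, Stat3, Il4ra and Nfil3 were higher in female fat. Tnfaip3 held 100.1 ± 1.65 CPM against 44.8 ± 2.20 CPM on chromosome 10 from 19060610 to 19064261 (1.16 ± 0.17, n = 2 per group, edgeR quasi-likelihood test with Benjamini-Hochberg adjusted p = 6.22e-08). Stat3, a factor downstream of IL-6 and IL-10 family cytokines, held 3.90 ± 0.295 against 0.330 ± 0.124 CPM on chromosome 11 from 100934078 to 100934471 (3.41 ± 0.54). Il4ra held 29.9 ± 4.58 against 12.1 ± 0.555 CPM (1.31 ± 0.20), and Nfil3 11.01 ± 1.63 against 4.03 ± 0.382 CPM (1.44 ± 0.27). Foxp3 had 4 of 6 regions higher, with 30.0 ± 4.05 against 13.6 ± 0.0174 CPM (1.14 ± 0.21), where the median of all X regions was 0.64.

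At Il1rl1, Pparg, Klrg1, Ccr2, Il10, Gata3, Prdm1 and Tcf7 edgeR, DESeq2 and limma-voom called 0 regions in either direction. At an unadjusted p under 0.05 edgeR counted 2 higher at Il1rl1, 1 at Ccr2, 3 at Il10, 1 at Tcf7, 1 higher and 3 lower at Gata3, 2 lower at Prdm1, and 0 at Pparg and Klrg1. The leading Klrg1 region held 2.27 ± 0.108 against 1.20 ± 0.0129 CPM (0.91 ± 0.47), and the leading Ccr2 region 3.06 ± 0.182 against 1.05 ± 0.116 CPM (1.51 ± 0.50, adjusted p = 0.119 in edgeR). Whether the sexes differ at these genes is tested by male against female VAT Tregs, since both share the spleen libraries.

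NF-kB factors had 10 of 91 regions higher and 0 lower (18 and 0 adjusted over the list alone, camera adjusted p = 2.01e-08, and adjusted p = 0.971 with an estimated correlation). VAT Treg genes had 9 of 148 higher and 0 lower (10 and 1, 0.0161), and Th17 genes 4 of 41, all at Rora, and 0 lower (7 and 0, 0.0161), both with adjusted p = 0.971 with an estimated correlation. Th1 genes had 1 of 76, at the IL-12 receptor gene Il12rb2, and 0 lower (7 and 0, 0.0206), and chemokine receptors 2 of 77, at Ccr1 and between Cx3cr1 and Ccr8, and 0 lower (2 and 0, 0.0435), again with adjusted p = 0.971 with an estimated correlation. The Il12rb2 call was lost without female replicate 1 or 2 (0.267 and 0.312) and spleen replicate 1 or 2 (0.190 and 0.299), and that of Ccr1 without female replicate 1 or 2 (0.0532 and 0.187) or spleen replicate 2 (0.222). The VAT Treg list was lost without female replicate 2 (0.148) or spleen replicate 2 (0.0608). Th17 was lost without spleen replicate 2 (0.0608), Th1 without spleen replicate 1 (0.138). The chemokine receptors were lost without female replicate 2 (0.148), spleen replicate 1 (0.159) or spleen replicate 2 (0.0866) and with genes within 20 kb (0.183). The AP-1 gene Fosl2 (1.17 ± 0.18), Tox (1.02 ± 0.20) and Elovl6 (1.63 ± 0.32) were higher without any 1 library, and Rora (2.16 ± 0.45) was lost without spleen replicate 2 (adjusted p = 0.0702, edgeR). X-linked escape genes had 28 of 42 regions higher in females (adjusted p = 0.0105 with an estimated correlation), led by Firre, a noncoding RNA locus, at 2.21 ± 0.26, and Y-linked genes 3 of 4 lower (0.00501). Over the 5 lists of other cell types edgeR called 0 of 115, with 3 higher and 5 lower at an unadjusted p under 0.05 and 0 by DESeq2 and limma-voom. The other 15 lists had camera adjusted p of 0.0747 to 0.936. Medians and means differed in sign for B cell markers and steroid hormone genes, and the tissue repair test went down with a median of 0.02 and a mean of 0.02.

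Among the largest falls in female fat were the male-only regions named above: Jdp2 was at least 31.4-fold lower and Htr6 with Tmco4 at least 14.3-fold lower in females, and Prkag2 had 2 counts against 177 (ratio 65.7, interval 17.9 to 546). Cnrip1, which binds a cannabinoid receptor, held 0.552 ± 0.216 against 8.28 ± 1.83 CPM (-3.89 ± 0.45). Alg2 (-4.45 ± 0.62), Slc10a2 (-3.69 ± 0.73) and Rerg (-3.27 ± 0.50), also among the 12 male-only regions, were lower without any 1 library. Bbs10 and Chl1 lost their calls without at least 1. The regions of Alg2, Bbs10 and Chl1 lay 29.2, 59.5 and 57.9 kb from these genes. Of the 10 largest higher in female fat, 9 lost their calls without at least 1 library: Mxi1, Atxn1, Swap70, Nck2, Cdk14, Ube2j2, Zfp281, Klhl5 and a T cell receptor alpha J region.

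In all, 363 autosomal regions were higher and 79 lower in female VAT Tregs than in male spleen Tregs, with 3694 at an unadjusted p under 0.05 in edgeR. On X, 178 were higher and 1 lower, and on Y, 0 higher and 10 lower. The counts were 134 and 24 without female replicate 1, 169 and 28 without female replicate 2, 202 and 36 without spleen replicate 1 and 161 and 55 without spleen replicate 2. They were 440 and 137 without male VAT Treg replicate 1 and 465 and 143 without male VAT Treg replicate 2. A fit of the compared groups alone gave 573 and 273, and the DESeq2 Wald test 152 and 26.

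Male VAT Tregs were compared with Foxp3 reporter-negative CD4 T cells of the same tissue and sex. Regions assigned to Foxp3, Ikzf2 and Prdm1 were higher in the reporter-positive cells, and regions assigned to Tcf7 and Lef1 in the negative ones. The leading Prdm1 region lay 148 kb from the gene and the leading Tcf7 region 30.7 kb. Foxp3 had 4 of 6 regions higher, with 16.4 ± 3.43 against 1.85 ± 0.440 CPM on chromosome X from 7582208 to 7585993 (3.12 ± 0.31, n = 2 per group, edgeR quasi-likelihood test with Benjamini-Hochberg adjusted p = 3.31e-18). Ikzf2, the Treg factor Helios, held 7.82 ± 2.02 against 1.61 ± 0.444 CPM (2.32 ± 0.40), and Prdm1 8.80 ± 2.79 against 1.78 ± 0.478 CPM (2.34 ± 0.40). Tcf7 had 4 of 9 regions lower in Tregs, with 1.95 ± 1.10 against 16.4 ± 4.95 CPM on chromosome 11 from 52314131 to 52314602 (-2.99 ± 0.31), and its partner Lef1 held 17.1 ± 0.0767 against 37.2 ± 2.24 CPM (-1.12 ± 0.20).

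Treg core genes had 35 of 149 regions higher and 2 lower in VAT Tregs (43 and 4 adjusted over the list alone, camera adjusted p = 9.96e-08), and VAT Treg genes 47 of 148 and 2 (68 and 4, 4.79e-18), both with adjusted p = 0.669 with an estimated correlation. NF-kB factors had 21 of 91 and 0 (30 and 1, 3.07e-08), Th17 genes 11 of 41 and 1 (16 and 2, 4.24e-07) and Th2 genes 14 of 53 and 2 (21 and 2, 2.57e-05). These 3 too had adjusted p = 0.669 with an estimated correlation. Klrg1 (3.31 ± 0.36), Rora (3.798 ± 0.51), Ctsh (3.38 ± 0.48), Nfkb1 (2.21 ± 0.37) and Plin2 (2.74 ± 0.42) were higher in each fit that left out a library. The triglyceride enzyme gene Dgat2 had 156 counts against 1, a ratio of 75.2 with an interval of 13.3 to 2988. Il1rl1 had 5 of 9 regions higher (2.54 ± 0.46), Pparg 2 of 4 (3.00 ± 0.58) and Il10 3 of 12 (1.16 ± 0.25). Gata3 had 2 higher and 1 lower of 13, led 173 kb from the gene (72 counts against 3, ratio 11.6, interval 3.803 to 57.4). Without male VAT Treg replicate 1 these gave adjusted p of 0.640, 0.146, 0.256 and 0.445 in edgeR. Without VAT CD4 replicate 1 Il10 gave 0.0677, and without VAT CD4 replicate 2 Gata3 gave 0.115. The NF-kB and Th2 list tests gave 0.0974 and 0.134 without male VAT Treg replicate 1. Ccr2, with regions 21.9 and 33.2 kb from the gene, had 0 of 2 called by edgeR, DESeq2 and limma-voom. It had 0 at an unadjusted p under 0.05.

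Naive and lymphoid homing genes had 8 regions higher and 25 lower of 128 in Tregs (12 and 33 adjusted over the list alone, camera adjusted p = 1.25e-05, and adjusted p = 0.669 with an estimated correlation). Ccr7 had 4 counts against 48 (-4.54 ± 0.82) and Il6ra was at -2.44 ± 0.49. TNF receptors and costimulation went both ways, with 28 higher and 10 lower of 140 (33 and 11, 0.000112, and adjusted p = 0.669 with an estimated correlation). Pdcd1 (1.98 ± 0.25) and Tnfrsf9 (1.24 ± 0.19) were higher, and the co-stimulator Cd28 (-1.68 ± 0.32) and the inhibitory receptor Btla (-2.34 ± 0.46) lower. Cytokine receptors had 28 higher and 10 lower of 158 (37 and 12, 0.0491, and adjusted p = 0.828 with an estimated correlation). Il1r2, the decoy IL-1 receptor, was at 1.32 ± 0.22 and Il12rb2 and Tgfbr3 at -1.95 ± 0.27 and -3.35 ± 0.51. Tissue repair and suppressive effectors had 12 higher and 1 lower of 72 (16 and 1, 0.00798, and adjusted p = 0.680 with an estimated correlation). The growth factor gene Areg was at 0.89 ± 0.20. Activation and exhaustion factors had 15 and 3 of 131 (16 and 5, 0.0466, and adjusted p = 0.828 with an estimated correlation). In the fit without male VAT Treg replicate 1 the last 4 list tests gave 0.0737 for TNF receptors, 0.924 with the direction turned for cytokine receptors, 0.533 for tissue repair and 0.642 for activation factors, whose test with genes within 20 kb gave 0.149. Without VAT CD4 replicate 1 the last 3 gave 0.714, 0.182 and 0.961, and the cytokine receptor test gave 0.0530 and 0.0535 without female replicate 1 and 2 and 0.0540 and 0.0526 without spleen replicate 1 and 2.

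B cell markers had 1 region higher and 3 lower of 24 in Tregs (1 and 3 adjusted over the list alone, camera adjusted p = 0.0460, and adjusted p = 0.669 with an estimated correlation). Pou2af1 was at -1.42 ± 0.24. The list test was lost without VAT CD4 replicate 2 (0.333), male VAT Treg replicate 1 (0.0511) or replicate 2 (0.138), with genes within 20 kb (0.177) and with scaling on regions under 1000 bp (0.0654). Prf1, the perforin gene of cytotoxic cells, was at -2.37 ± 0.48. Over the 5 lists of other cell types edgeR called 2 higher and 6 lower of 115 in Tregs. The other 11 lists had camera adjusted p of 0.0506 to 0.953, and medians and means differed in sign for chemokine receptors (test down) and lipid genes (test up), at medians of -0.06 and -0.06. Myeloid markers had a median of 0.11 and a mean of 0.01 with the test downwards, and X-linked escape genes a mean of -0.02 with the test upwards. The chemokine receptor Cxcr6 was lower at -1.34 ± 0.24.

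Of the 10 largest falls in Tregs, 9 lay in the T cell receptor alpha locus, singled out after its values were seen, and the other was at Ccr7. Of its 37 regions under 1000 bp on chromosome 14 between 53039559 and 54153131, 33 were lower in male VAT Tregs than in VAT CD4 cells and 0 higher. There were 0 higher and 36 lower at an unadjusted p under 0.05 in edgeR, 30 lower by DESeq2 and 33 by limma-voom. The mean per region was 5.08 ± 3.21 CPM in VAT CD4 cells, from 7.34 in replicate 1 and 2.81 in replicate 2, against 0.436 ± 0.111 in male VAT Tregs, 1.32 ± 0.106 in female VAT Tregs and 0.690 ± 0.0476 in spleen Tregs. Trav6-7-dv9 with Trav7-6 and Trav13-3 had 1 count in male VAT Tregs against 64, a ratio of 133 with an interval of 23.0 to 5327. Against female VAT Tregs edgeR called 12 lower in males, 37.5% of the 32 autosomal regions under 1000 bp called lower, DESeq2 5 and limma-voom 6, and 7 of the 8 named above lost their calls without at least 1 library. Of the largest rises, Rbks with Bre was at least 19.6-fold higher in Tregs (122 counts against 0). Coro2a had 138 against 2 (ratio 33.3, interval 9.03 to 277) and Ceacam15 134 against 1 (64.6, 11.4 to 2569). The calls of Raph1, Slc25a1, Epb4.1l4a, Dleu2 and Gpr55 were lost without at least 1 library (adjusted p of up to 0.211, Gpr55, edgeR).

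**Figure D4:**
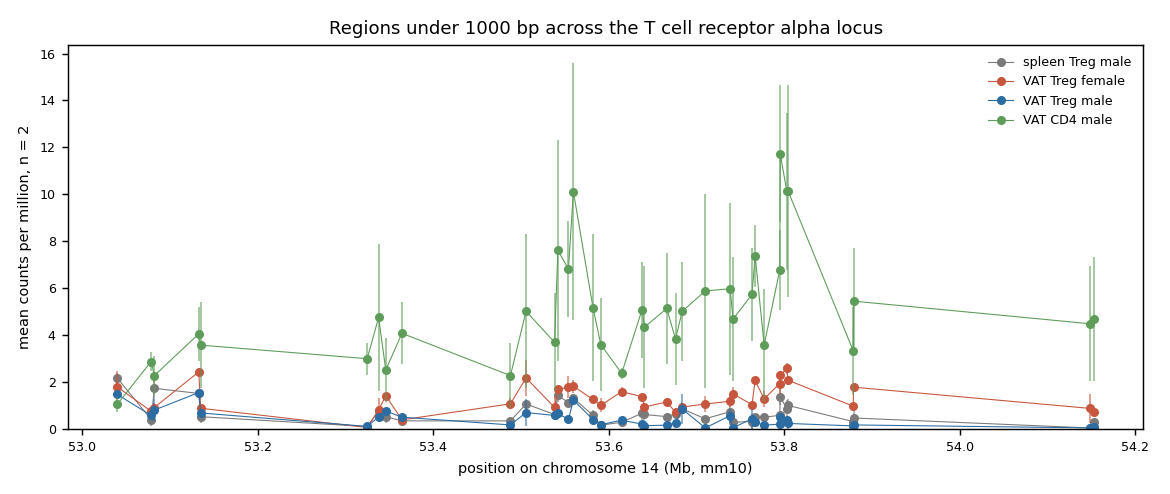
Mean CPM of 2 libraries at 37 regions under 1000 bp, by position in Mb along the T cell receptor alpha locus, one line per group; vertical strokes join the values of the 2 libraries. The mean per region was 5.08 in VAT CD4 cells and 0.436 in male VAT Tregs.

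In all, 2320 autosomal regions were higher and 1138 lower in male VAT Tregs than in VAT CD4 cells, 67.1% of them higher, with 7983 at an unadjusted p under 0.05 in edgeR. The counts were 829 and 794 without male VAT Treg replicate 1 (51.1% higher), 1156 and 718 without VAT CD4 replicate 1 and 1532 and 636 without VAT CD4 replicate 2. Scaling on regions under 1000 bp gave 1124 and 1884 (37.4% higher), and library size alone 2814 and 667 (80.8%), where the median log2 fold change of all autosomal regions moved from -0.02 to 0.11.

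At regions higher in male VAT than in spleen Tregs, the median of female VAT Tregs lay between those groups. Over 1105 regions chosen on the replicate 1 libraries as at least 4-fold higher in male VAT than in spleen Tregs, the replicate 2 libraries gave a median log2 difference from spleen of 1.31 in males (quartiles 0.73 and 1.97) and 0.55 in females (-0.02 and 1.12). The female difference was 42.1% of the male one and lay below it in 80.4% of regions, with females above spleen in 73.2%. With the libraries swapped, 453 regions gave 2.21 in males and 0.38 in females, 17.2%, with the female below the male in 93.6% and above spleen in 65.6%. The regions were chosen on males alone, which favours a female median below the male one. Neither regions lower in male VAT nor regions chosen on female VAT Tregs were examined this way. No test was made of this position.

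Of the 924 autosomal regions higher in male than in female VAT Tregs, 729 were also higher in male VAT than in spleen Tregs, where independent sets of these sizes would share 43.1, and 137 of the 335 lower were lower in both (7.12). Klrg1, Ctsh and Plin2 were among the genes higher against female VAT Tregs, and Klrg1 and Plin2 were among those named against spleen. The comparisons share the male VAT Treg libraries. Their log2 fold changes had a covariance of 0.232 across regions against 0.0562 in 20 simulated sets without differences. Those sets gave 0 shared calls, which was largely fixed by drawing them without differences. They also lacked the larger share of counts in regions under 1000 bp in male VAT Treg replicate 1. Neither value is therefore a baseline for the 729 shared regions. The overlap of sex and tissue regions, higher, was 137 without male VAT Treg replicate 1, 232 without female replicate 1 and 272 without female replicate 2. The overlap of sex and tissue regions, lower, was 513, 28 and 9 without these and 86 without male VAT Treg replicate 2, 48 without spleen replicate 1 and 49 without spleen replicate 2. Of the 363 regions higher in female VAT Tregs than in spleen, 310 were also higher in male VAT Tregs than in spleen. These 2 comparisons share the spleen libraries. Their log2 fold changes had a covariance of 0.180 against 0.0575 in the simulated sets, whose 0 shared calls are again no baseline.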

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

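The tests on the split without male VAT Treg replicate 1, on Y-linked repeats, on other cell types and on V to J joining were chosen after the results were seen. The scaling on regions under 1000 bp was added after the data were seen, with its threshold set before its result. Signal outside the comparisons was found in the mitochondrial region, which took 22.6 to 34.1% of the counts of a library.

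More autosomal regions were higher than lower in male than in female VAT Tregs (924 against 335). The excess lay in regions under 1000 bp (762 higher and 32 lower), whereas regions of 1000 bp or more gave 162 higher and 303 lower. With factors from regions under 1000 bp, the share of calls higher in male VAT Tregs was 48.8% against spleen Tregs and 37.4% against VAT CD4 cells. Against female VAT Tregs it was 66.2%, with 457 of the 924 higher calls kept. That value argues against scaling set by the broad regions as the whole cause of the split between the sexes, but not as a part of it. The fit still held male VAT Treg replicate 1. The split rested on male VAT Treg replicate 1: without it 19.2% of the calls were higher, so a stronger signal over background in that library is a candidate explanation of the split. That library alone does not account for the direction at regions chosen as at least 4-fold higher in males on the replicate 1 libraries. These 571 regions were all under 1000 bp. Between the replicate 2 libraries they differed by a median of 1.32 on the log2 scale, 93.3% of them above 0. With the libraries swapped, 244 regions differed by a median of 1.89 between the replicate 1 libraries, 91.8% above 0. The test bears on direction and not on a 4-fold size. It was written for the whole split and narrowed to these regions afterwards. A difference between the sexes stays open for them, untested beyond these libraries.

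At Jdp2, Prkag2 and 10 other autosomal regions under 1000 bp, all 6 male libraries had counts and the mean of the 2 female libraries was under 25% of the lowest male value. Reads of Y-chromosome repeats placed on autosomes may account for them: over the 6 male libraries their mean log2 CPM followed that of the 2 Y regions of highest CPM (r = 0.955, exact permutation p = 0.0264, adjusted p = 0.0528 over 2 relations; rho = 0.771, exact p = 0.103). Those Y regions held 104.3 to 410.6 CPM in males and 0.821 to 2.19 in females, and r was 0.700 without the 2 libraries farthest from the median. With the 3 Y genes r was 0.0896 (exact p = 0.951). The 2 explanations, such reads and a difference between male and female chromatin, cannot be told apart here, since the adjusted p misses the threshold and the second was not tested.

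The T cell receptor alpha locus had more signal in VAT CD4 cells than in male VAT Tregs, by a median of 3.98 on the log2 scale over 37 regions. The mean per region was 7.34 and 2.81 CPM in the VAT CD4 libraries. All Treg groups were lower, at 0.436 in male VAT, 0.690 in spleen and 1.32 in female VAT. Of the 37 regions, edgeR called 0 lower in male VAT than in spleen Tregs and 12 lower than in female VAT Tregs. Cells of another type in the VAT CD4 libraries would raise their markers. The highest of the 5 list medians was 0.218. Of the 115 regions on these lists, edgeR called 6 higher and 2 lower in VAT CD4 cells than in male VAT Tregs. The regions had a median of 4.81 CPM in male VAT Tregs, and the most abundant, at Cr2, held 114.8 to 170.3 CPM in all libraries. A small share of other cells could therefore not be seen in the medians. The sort for CD4 would remove most such cells. The difference between VAT CD4 cells and male VAT Tregs grew along the V segments towards the J segments (Spearman rho = 0.794 across regions, which are not independent). More DNA of the locus cut out by V to J joining in male VAT Tregs than in VAT CD4 cells would give such a trend. That trend does not separate the explanations, because cells with an unjoined locus in the VAT CD4 libraries would give it too. A difference in chromatin between the cell types was not tested.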

How the results depend on the processing

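TMM on regions under 1000 bp and limma on the deposited log2 values were chosen after the data were seen. With 1 library left out, the regions called higher and lower ranged from 224 to 1245 and 16 to 941 in male against female VAT Tregs, from 704 to 2452 and 310 to 1016 against spleen, from 134 to 465 and 24 to 143 in female VAT Tregs against spleen, and from 829 to 2719 and 636 to 1214 against VAT CD4 cells. Lists called ranged from 10 to 14, 5 to 13, 4 to 8 and 4 to 13 in that order, and the regions shared by the sex and tissue comparisons from 137 to 991 higher and 9 to 513 lower. Among the named regions, 2049 of the leave-one-out results were the same, 426 lost their call, 1 gained it and 2 changed direction, and 3323, 342, 1 and 0 under other settings.

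In the same order, the DESeq2 Wald test gave 346 and 47, 1096 and 248, 152 and 26, and 1228 and 607. An adjusted p under 0.01 gave 522 and 83, 1331 and 299, 222 and 34, and 1411 and 607, by construction fewer. A 2-fold minimum left 45, 265, 51 and 698 lower. Limma on the deposited log2 values gave 418 and 212, 1335 and 555, and 40 lower for female VAT Tregs against spleen. TMM on regions under 1000 bp gave 457 higher, 1230 higher, 144 and 32, and 1124 and 1884. Library size alone gave 164 lower in the first, 235 higher in the third and 667 lower in the fourth, loess offsets 208 lower in the first, limma-voom 1481 higher in the fourth, and a fit of the compared groups alone 573 and 273 in the third. With an estimated correlation 2, 0, 2 and 0 lists were called, and 2, 0, 2 and 0 at an unadjusted p under 0.05. The position with libraries swapped was 17.2%. The overlap of sex and tissue regions, higher, was 410 at an adjusted p under 0.01 and 361 with TMM on regions under 1000 bp, and the overlap of sex and tissue regions, lower, 22 at an adjusted p under 0.01. Same-numbered libraries of different groups shared only a number, their deviations from the group means correlating at -0.146 to 0.0666, and the replicate number as a block gave 780 and 226, 1796 and 657, 294 and 61, and 2050 and 949.

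Direction changed for the NF-kB list in male against female VAT Tregs without male replicate 1 (camera adjusted p = 0.701, and 5.17e-12 without replicate 2) and the cytokine receptor list against VAT CD4 cells without that library (0.924, and 0.000257 without replicate 2), and for uncalled Ccr2 regions in male against female VAT Tregs without male replicate 2 (0.10, and -1.14 without replicate 1) and against VAT CD4 cells without male replicate 1 (-0.010, and 0.50 without replicate 2). The cause was not tested for any of these. With 2 libraries per group, 50 to 60 of 100 regions changed 2-fold were found in simulated data. The simulated libraries shared the same mean profile apart from the changed regions, so the limit in the real libraries was not measured. A correction for GC content and promoter-only lists were not run.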

Other observations

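No test here was chosen after its result was seen. In male against female VAT Tregs, 3 genes each of the Treg core, Th1 and tissue repair lists, which did not pass, had regions called higher by edgeR (n = 2 per group, Benjamini-Hochberg adjustment), and 1 gene each of the first and last had regions called lower, Foxp3, given above, and Osm, lost without female replicate 1 or 2 (0.0741 and 0.628) or male replicate 2 (0.232). Values of 4 of those higher follow. Furin, a protease gene, held 13.2 ± 8.61 against 3.73 ± 0.199 CPM (log2 fold change 1.86 ± 0.29), Nrp1, a surface receptor of Tregs, 4.44 ± 2.06 against 0.786 ± 0.548 CPM (2.55 ± 0.54), Hopx 4.07 ± 1.23 against 0.508 ± 0.552 CPM (2.93 ± 0.63), and Ikzf2 6.69 ± 2.82 against 2.70 ± 0.00428 CPM (1.33 ± 0.38). Without male replicate 1 the adjusted p were 0.196, 0.209, 0.124 and 0.484. Without female replicate 1 those of Nrp1 and Ikzf2 were 0.180 and 0.274, and without female replicate 2 those of Hopx and Ikzf2 were 0.176 and 0.252. The DESeq2 Wald test gave 0.201 for Furin and 0.184 for Ikzf2, and scaling on regions under 1000 bp and limma on the deposited log2 values gave 0.0743 and 0.145 for Ikzf2.

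Among males, edgeR called 36 X regions higher and 4 lower in VAT than in spleen Tregs, and 0 higher and 3 lower on Y, where 8 had an unadjusted p under 0.05. In VAT Tregs against VAT CD4 cells the counts were 48 and 6 on X and 0 and 2 on Y, where 6 had an unadjusted p under 0.05.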
